A study of Homo sapiens with 7 samples.

How the data were processed

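The samples were 7 Seq-Well libraries of day 42 forebrain organoids from the H9 line, 4 homozygous for the RING1 missense change and 3 wild type, grouped by the genotype in their labels. Per the labels' protocols, Nextera XT libraries of polyadenylated RNA were sequenced on an Illumina NextSeq, and organoids were shaken at 95 rpm at 37 °C with 5% CO2. Each deposited table holds UMI counts per gene and barcode, whole numbers that were not normalized. The genome build was hg38, per the submitters' processing notes; the aligner, the annotation and the counting rules are not given in the sources used here. Every barcode in the deposited tables had at least 300 genes and 311 UMIs, so barcodes below some limit had been left out before deposit. The series' design text speaks of bulk sequencing of progenitor cells, while the counts are per cell. Gene positions were taken from GENCODE release 29 (GRCh38, the same coordinates as hg38) by gene symbol, which placed 85.9%, 92.1% and 93.1% of tested genes in all cells, progenitor-like and neuron-like cells.

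The 7 tables held 52090 barcodes and 45409 genes. A barcode was kept with at least 500 UMIs, at least 300 genes and under 20% of UMIs from mitochondrial genes, which left 40418. Kept barcodes and UMIs were 6966 and 12077733, 4943 and 13221195, 5512 and 8304918, and 4194 and 5853005 in missense replicates 1 to 4, and 7696 and 10110577, 4037 and 10540344, and 7070 and 14110993 in wild-type replicates 1 to 3. The median mitochondrial share ran from 2.93% to 7.17% of UMIs. The 9 pairs of libraries within a genotype differed by 11.8 to 136 times their sampling noise (chi-square per degree of freedom), so no library was counted as a copy of another. Scrublet called 9 of 40418 barcodes doublets (0.0223%), a share at which the caller has not worked, so doublets were in effect left in; an alternative left out the 5% of barcodes with the most UMIs.

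Counts were scaled to the median total and log-transformed in scanpy 1.11.5 (Python 3.11.15). From 2000 highly variable genes chosen within libraries, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave clusters without integration across libraries. A cluster was named after the class with the most markers among its 100 leading genes by fold, with at least 3 markers; a cluster with more than 5 mitochondrial genes among its 10 leading genes stayed unnamed, a rule set after the clusters were seen. Clusters numbered 3 and 15 also stayed unnamed, for too few or mixed markers, with 1.16 ± 0.515% of missense and 0.797 ± 0.453% of wild-type barcodes (SD, n = 4 and 3).

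Cells are not replicates, so counts were summed per library over all kept barcodes, over progenitor-like and over neuron-like cells. The sums were tested between genotypes with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), with TMM normalization, its default low-count filter, robust fitting and Benjamini-Hochberg adjustment at 0.05. The difference of the genotype effect between the 2 classes was tested as an interaction with the library as a block. CPM values are the summed counts scaled by library size and TMM factor. Lists were tested with fry of limma 3.58.1 on voom values, which asks whether the genes of a list move one way on balance and does not set the list against other genes, and, as alternatives, with camera at a preset correlation of 0.01 and with an estimated correlation. Of 41 lists fixed before the data were examined, along with the tests, the filters on barcodes, the cell type markers and the naming rule, those with at least 3 measured members were tested; 825 of their 864 symbols were found in the tables.

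Shares of cell classes and of cell-cycle phases were compared with two-sided exact permutation tests over the 35 assignments of the 7 libraries. Phases were scored with scanpy after each cell was thinned to 1000 UMIs, and without thinning. Named genes were RING1 and RNF2; per comparison, up to 10 rises and 10 falls past the threshold with at least 20 CPM in a genotype and no overlap between the genotypes; with fewer than 10 of these, also the 10 with the smallest p; and members of described lists with the smallest p or the highest level. Other genes past the threshold are named as chosen after their values were seen. A fold against a group with no count used a floor of 3 counts over the group, and ratios of small counts have 95% intervals that cover counting error only. Intervals of a median over genes resample the genes and leave out the spread between libraries.

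Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors in edgeR, no low-count filter, at least 10 CPM in 3 libraries, mitochondrial and ribosomal protein genes left out, libraries thinned to the smallest total, the replicate number as a block, each library left out, other barcode filters and other clusterings. Chosen after the data were examined were the fits without 2 libraries that stood apart in make-up, fits with 1 or 2 surrogate variables from sva 3.50.0, the setting without the barcodes of most UMIs, the scan along the chromosomes (median of 20 neighbouring genes with a mean of at least 20 CPM) and the count of X-linked genes among the 100 smallest p. Other window layouts were also looked at in that scan. The X-linked count took the 100 smallest p among the genes used in the scan. The surrogate-variable fits have no count over other splits of the samples.

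The gene tests were tested on simulated counts with the means and library sizes of the real libraries and 200 changed genes. They recovered 4.48%, 61.2% and 78.8% of changes of 2, 4 and 8-fold in all cells over 16313 genes, 34.3%, 88.1% and 90.9% in progenitor-like cells over 12767, 25.4%, 77.6% and 90.9% in neuron-like cells over 12126, and 11.9%, 70.1% and 87.9% for the interaction over 11860. A simulated list of 15 random genes changed 1.5-fold gave adjusted p = 0.262, 0.0171 and 0.00593 by fry over 21 lists in the 3 cell sets. Each value came from a single draw with noise independent between genes, so it gives no rate of detection for the real lists. The scan placed its highest window in a simulated block of 30 genes raised 1.5-fold in 100 of 100 simulated maps of 8246 genes. The simulated noise was independent between genes, and maps without a block had no window beyond 0.332. In the real libraries another split reached 0.631, so the simulation does not show how well the scan finds such a block in these data.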

Results

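Single-cell transcriptomes were measured in human forebrain organoids carrying a missense change in RING1 and in wild-type organoids. RING1 is a ubiquitin ligase of Polycomb repressive complex 1 (PRC1), which, like its paralogue RNF2, attaches a single ubiquitin to histone H2A. The cells were H9, an established human embryonic stem cell line, edited with CRISPR-Cas9 and differentiated by inhibition of both SMAD branches. Per the labels, organoids were moved to suspension culture after day 14 and taken at day 42, although the tissue label of the same samples names a progenitor monolayer. The data comprised 4 libraries homozygous for RING1 R95Q (missense) and 3 wild-type libraries, made with Seq-Well, a microwell method that counts the 3′ ends of transcripts with unique molecular identifiers (UMIs). The series asks how the dose of H2A ubiquitination acts on gene expression and on DNA repair in neural cells. The filters left 21615 missense and 18803 wild-type barcodes, with 5853005 to 14110993 UMIs per library and median UMIs per barcode of 964 to 1646. No label states that the libraries of a genotype came from separate cultures, so p-values measure the spread between these samples, which may be technical.

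RING1 and RNF2 transcripts did not pass the test of a difference between the genotypes. RING1 (chromosome 6, 33208495 to 33212722, hg38) stood at 63.6 ± 10.8 CPM (counts scaled by library size, SD, n = 4) in missense libraries summed over all cells and at 74.7 ± 10.4 CPM (n = 3) in wild type, a log2 fold change of −0.23 ± 0.19 (SE, adjusted p = 0.779). Its change was −0.28 in progenitor-like cells and −0.02 in neuron-like cells (adjusted p = 0.697 and 0.983). RNF2 (chromosome 1, 185045364 to 185102608) stood at 34.2 ± 7.55 CPM (n = 4) and 31.5 ± 4.16 CPM (n = 3), with changes of 0.12, 0.22 and 0.10 in all cells, progenitor-like and neuron-like cells (adjusted p = 0.899, 0.796 and 0.894). The 3′ counts do not cover the edited codon, so these levels do not check the genotype labels.

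The organoids held progenitor-like cells (clusters led by SFRP1, HEY1, histone or mitotic genes), neuron-like cells, intermediate progenitor-like cells led by EOMES and NHLH1, and choroid plexus or roof plate-like cells led by TTR and RSPO2. Neuron-like clusters were led by DLX5 and GAD2, genes of inhibitory neurons, by GNRH1 and NEFL, by FOXP2 and RELN, by NEUROD2 and NEUROD6, genes of excitatory cortical neurons, or by ONECUT2. Progenitor-like cells made up 47.7 ± 18.9% (SD, n = 4) of missense and 29.1 ± 27.6% (n = 3) of wild-type barcodes, a difference smaller than the spread between libraries (exact permutation p = 0.314). Neuron-like cells made up 22.3 ± 7.24% and 42.4 ± 40.6% (exact p = 0.543), intermediate progenitor-like cells 5.13 ± 3.66% and 4.77 ± 6.29% (exact p = 0.943), and choroid plexus or roof plate-like cells 8.23 ± 6.41% and 19.1 ± 32.7% (exact p = 0.857).

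The wild-type libraries differed most from each other in make-up. Neuron-like cells took 88.7% of wild-type replicate 1 and 12.7% of wild-type replicate 3, where choroid plexus or roof plate-like cells took 56.9%. Within the missense group the neuron-like share ran from 15.1% to 29.7% and the progenitor-like share from 25.6% to 69.4%. The adjusted exact p was 0.943 for each of the 4 classes, and the smallest p that 35 assignments of the libraries allow is 0.0286. Barcodes in no named class were 43.3% of missense replicate 1 and 0.6% to 14.8% of the others. Most of them were in a cluster led by mitochondrial genes, which held 15.5 ± 18.4% of missense (n = 4) and 3.77 ± 6.02% of wild-type barcodes (n = 3). It was kept out of the classes by a rule set after its genes were seen. The class with the most markers among its leading genes, 4, was choroid plexus or roof plate, so the shares of that class may depend on the rule. At Leiden resolution 0.5, where no cluster stayed unnamed, choroid plexus or roof plate-like cells were 23.6 ± 23.5% of missense and 23.5 ± 39.7% of wild-type barcodes.

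**Figure D1:**
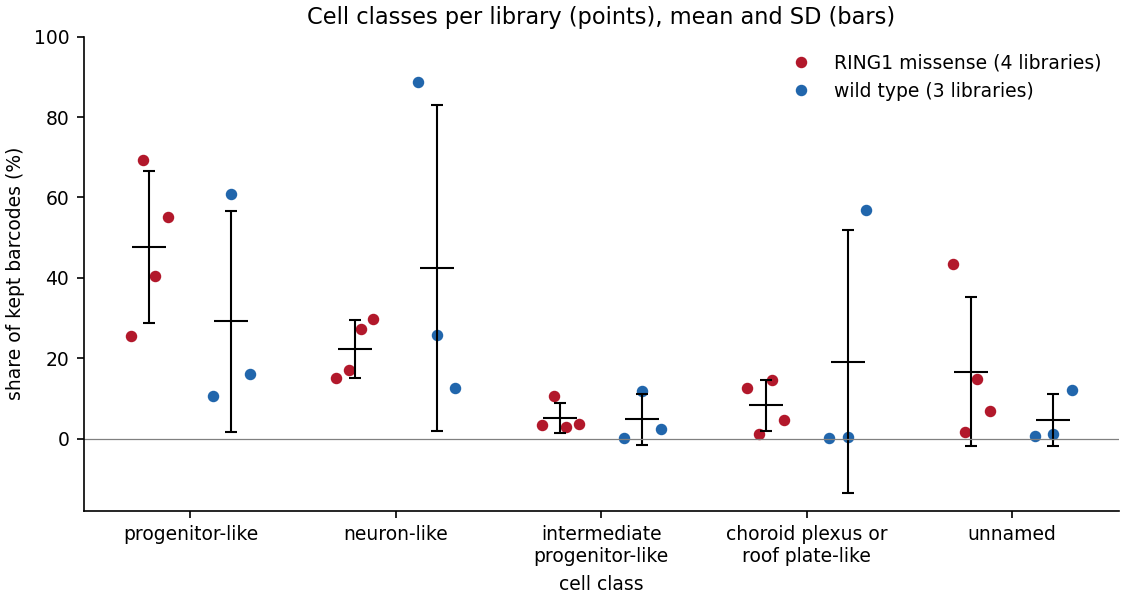
Share of kept barcodes (%) in each cell class, with 1 point per library (red, 4 missense libraries; blue, 3 wild-type libraries) and bars for mean and SD. The wild-type points lie as far apart as 12.7% and 88.7% in the neuron-like class, and the missense points lie between 15.1% and 29.7%.

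Summed over all cells, 1 gene differed between the genotypes. C17orf51, a little-studied open reading frame on chromosome 17 (21428381 to 21574517), stood at 0.092 ± 0.071 CPM (SD, n = 4) in missense libraries and 19.5 ± 5.26 CPM (n = 3) in wild type (log2 fold change −7.78 ± 0.57 SE, adjusted p = 0.0107). The missense libraries held 3 UMIs of it and the wild-type libraries 658, a ratio of 249 (95% counting interval 84.8 to 1210). Its level lay just under the 20 CPM of the naming rule, so it was chosen after its values were seen. USP9X, a deubiquitinase on the X chromosome, had 669 ± 20.8 CPM in missense and 325 ± 6.94 CPM in wild-type libraries and did not pass (log2 fold change 1.04, adjusted p = 0.160).

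The other genes with the smallest p in the sum of all cells also missed the threshold. EPHA3, an ephrin receptor of axon guidance, had a log2 fold change of 1.96 ± 0.25 (SE, adjusted p = 0.138), with 134.8 ± 35.1 CPM against 34.5 ± 6.85 CPM. FEZF1, a zinc-finger repressor of forebrain development, had 1.79 (adjusted p = 0.160). MYRF, a regulator of myelin genes, and the pseudogene ANKRD20A7P had 1.87 and 6.64 (adjusted p = 0.323 and 0.160). PCDHA6, a neuronal adhesion protein of the protocadherin alpha cluster, had −4.58, and TCEAL5, of the TCEAL family related to elongation factors, −6.45 (adjusted p = 0.123 and 0.160). CEBPZOS and CFLAR, an inhibitor of caspase 8, had −3.64 and −2.53 (adjusted p = 0.0524 and 0.390). ZNF736, a zinc-finger gene, had 0 UMIs in missense and 143 in wild-type libraries, at least 54.1-fold lower against a floor of 3 counts over the group (adjusted p = 0.126). EdgeR tested 16706 genes, of which 941 had an unadjusted p below 0.05. DESeq2 called 27 higher and 22 lower genes and limma-voom 0 and 3, and edgeR called 0 genes without missense replicate 1, 3 or 4 and 2 without wild-type replicate 3.

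In progenitor-like cells 3 genes were lower in missense libraries and 0 were higher. APOO, a component of the mitochondrial inner-membrane complex MICOS (chromosome X, 23833353 to 23907934), fell from 119 ± 17.7 CPM (SD, n = 3) to 46.7 ± 6.33 CPM (n = 4), a log2 fold change of −1.34 ± 0.17 (SE, adjusted p = 0.0445). C17orf51 fell from 19.7 ± 4.11 CPM to 0 (adjusted p = 0.00468), with 0 of 18382527 missense UMIs and 201 of 9805668 wild-type UMIs, at least 126-fold lower against a floor of 3 counts over the group. PCDHA6 (chromosome 5, 140827958 to 141012344) fell from 16.1 ± 7.97 to 0.399 ± 0.163 CPM (log2 fold change −5.22 ± 0.51 SE, adjusted p = 0.00468), 7 against 124 UMIs. Both lay under 20 CPM in each genotype and were chosen after their values were seen, and PCDHA6 shares its 3′ exons with the other protocadherin alpha genes, so its reads could be split between them.

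The next genes in progenitor-like cells did not pass. POLA1, the catalytic subunit of DNA polymerase alpha, stood at 96.4 ± 17.1 CPM against 221 ± 19.3 CPM (log2 fold change −1.19 ± 0.17 SE, adjusted p = 0.0602), and PRDX4, a peroxiredoxin of the endoplasmic reticulum, had −0.97 (adjusted p = 0.0776). USP9X had 1.04 (adjusted p = 0.0602), EPHA3 2.42 and SPINK5, a serine protease inhibitor, 1.93 (both adjusted p = 0.0776). SFMBT2, a Polycomb-group protein, had 1.37, the elongation factor ELL2 1.5, FEZF1 1.61 and the lipid kinase gene PIK3C2B 1.14 (each adjusted p = 0.112), and the calcium pump gene ATP2B4 1.10 (adjusted p = 0.124). PIK3C2B and ATP2B4 lie in the chromosome 1 stretch described below. Different clusters held most of this class in different libraries: cluster 9, led by MCM genes of DNA replication, held 45.2% of it in missense replicate 1 and 53.4% in wild-type replicate 3, and 0.7% to 27.1% in the rest. Of 12996 genes tested with edgeR, 1149 had an unadjusted p below 0.05; DESeq2 called 42 higher and 30 lower, limma-voom 0 and 2, and edgeR 2 to 4 in all with any 1 library left out. APOO lost its call in 15 of 26 alternative settings, among them the leaving out of any 1 library but wild-type replicate 2, and C17orf51 and PCDHA6 in 4 each.

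In neuron-like cells 1 gene rose and 4 fell. FEZF1 (chromosome 7, 122301394 to 122310691) rose from 7.56 ± 1.82 CPM (SD, n = 3) to 49.9 ± 13.4 CPM (n = 4), a log2 fold change of 2.69 ± 0.29 (SE, adjusted p = 0.0133). APOO fell from 87.7 ± 12.5 to 29.6 ± 5.58 CPM (−1.56 ± 0.20, adjusted p = 0.0327), C17orf51 from 22.1 ± 7.84 to 0.13 ± 0.261 CPM and PCDHA6 from 30.9 ± 12.5 to 1.76 ± 0.69 CPM (both adjusted p = 0.00892). C17orf51 had 1 UMI in missense and 256 in wild-type libraries, a ratio of 159 (95% counting interval 28.3 to 6306), and PCDHA6 had 15 and 490. TCEAL5 (chromosome X, 103273691 to 103276872) fell from 17.5 ± 9.03 to 0.126 ± 0.252 CPM (adjusted p = 0.0181), 1 UMI against 279 and a ratio of 173 (30.9 to 6871); it was chosen after its values were seen, and it has close copies in its family with which reads could be shared.

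**Figure D2:**
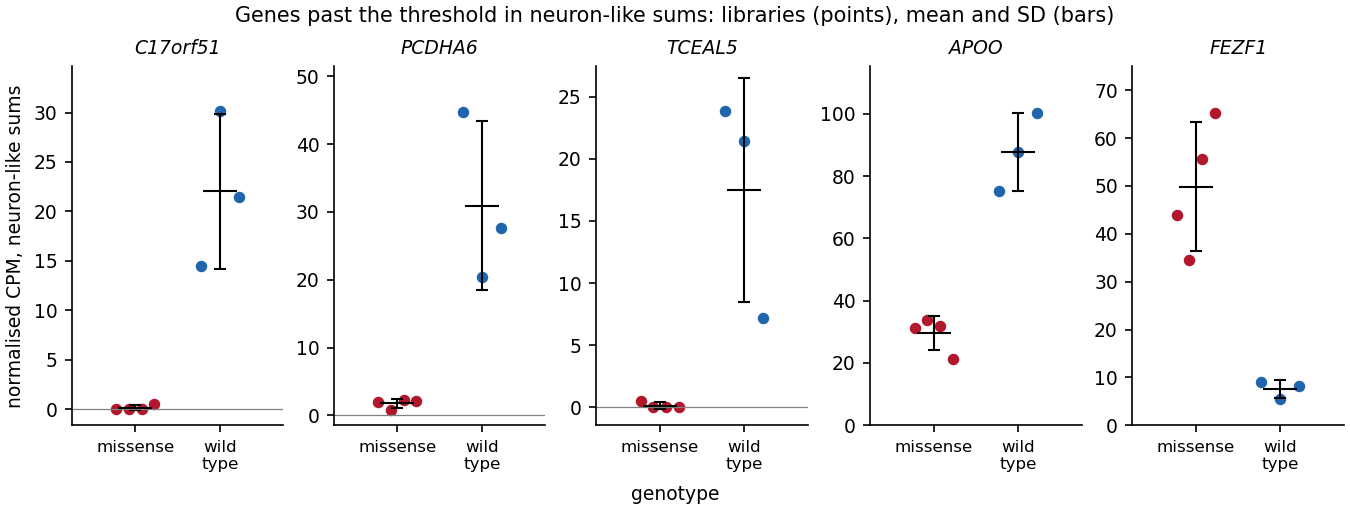
Normalised CPM in sums over neuron-like cells of the 5 genes past the threshold, with 1 point per library (red, 4 missense; blue, 3 wild-type) and bars for mean and SD; each panel has its own axis. FEZF1 is at 49.9 CPM on average in missense and 7.56 CPM in wild-type libraries, and the other 4 genes are lower in every missense library than in any wild-type library.

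Among neuron-like genes that did not pass, USP9X had a log2 fold change of 0.96 (adjusted p = 0.0588) and PCDHGA10, a gamma protocadherin, 1.31 ± 0.19 (SE, adjusted p = 0.0805). MEF2C, a transcription factor of maturing neurons, stood at 64.4 ± 19.0 CPM (SD, n = 4) against 180 ± 54.1 CPM (n = 3), a log2 fold change of −1.49 (adjusted p = 0.241). POLA1 had −1.10 and the long noncoding RNA LINC00657 −0.96 (adjusted p = 0.152 and 0.153). COL6A2, a collagen VI chain, had 1.49, the kinase gene NUAK2 1.42, the adhesion receptor gene ADGRB1 0.96, the chromatin gene PHF6 0.89 and ARRDC4 0.87 (adjusted p = 0.152 to 0.247). NUAK2 lies in the chromosome 1 stretch described below, and PHF6 is X-linked. The neuron-like class was made of different clusters: the FOXP2 and RELN cluster held 75.3% of it in missense replicate 1 and 0.952% in wild-type replicate 1, where the ONECUT2 cluster held 55.6%, and the NEUROD2 and NEUROD6 cluster held 60.6% in missense replicate 2 and 72.9% in wild-type replicate 2. Of 12342 genes tested with edgeR, 1104 had an unadjusted p below 0.05; DESeq2 called 33 higher and 20 lower and limma-voom 0. With edgeR, 0 genes passed without missense replicate 1, 3 or 4, 2 without wild-type replicate 1, 3 without missense replicate 2 or wild-type replicate 3, and 14 without wild-type replicate 2.

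Whether the effect of the genotype differed between neuron-like and progenitor-like cells was tested as an interaction. PLK2, a kinase induced by neuronal activity, had a log2 fold change of 0.92 in progenitor-like and 0.00 in neuron-like cells (adjusted p = 0.533 for the difference), MEF2C −0.27 and −1.49, and FEZF1 1.61 and 2.69 (adjusted p = 0.754 for both), so a difference of the FEZF1 effect between the classes was not shown. EdgeR called 0 of 13785 genes, with 555 at an unadjusted p below 0.05; no other tool was run on this comparison, and edgeR without the low-count filter called 5 higher and 53 lower.

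Genes of the PRC1 complex showed no common direction. In all cells 17 of its 33 measured members lay above 0 and 16 below, with a median log2 fold change of 0.02 (adjusted p = 0.895), and 0 members passed over all genes or adjusted over the list alone. The members with the smallest p included BCOR, a subunit of variant PRC1, at 0.43, 0.36 and 0.68 in all cells, progenitor-like and neuron-like cells. PRC2, which methylates histone H3, had medians of 0.05, 0.01 and 0.09, with its catalytic subunit EZH2 at −0.55 in progenitor-like cells (adjusted p = 0.477). Developmental regulators bound by Polycomb had medians of −0.19, 0.16 and 0.07 with 33, 18 and 14 members measured, and 0 of the HOX genes reached the count filter.

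DNA repair genes did not pass as groups. Homologous recombination and Fanconi anaemia genes had 34 of 36 members above 0 in all cells (median 0.33, adjusted p = 0.793 by fry) and medians of 0.05 and 0.21 within progenitor-like and neuron-like cells. Damage signalling and end joining genes had medians of 0.07, −0.11 and −0.02, and excision and mismatch repair genes −0.11, −0.15 and −0.15. BRCC3, an X-linked gene for a deubiquitinase of the BRCA1-A complex, had −0.50, −0.54 and −0.46 (0.40 in progenitor-like cells with libraries thinned to the smallest). XRCC5, the larger Ku subunit of end joining, had −0.33, −0.42 and −0.35, and adjusted p was 0.463 or more for both genes. XRCC6, the other Ku subunit, and H2AFX, the histone variant phosphorylated at breaks, had −0.40 and −0.68 in progenitor-like cells (adjusted p = 0.544 and 0.490). Targets of p53 had medians of 0.20, 0.14 and 0.02, and 0 members of the 3 repair lists passed adjusted over the list alone.

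Cell-cycle and neuronal genes each lay to one side in the sums of all cells. S-phase genes had 40 of 43 and G2/M genes 51 of 54 members above 0 there, and general neuronal genes 15 of 15 below 0 with a median of −0.67, where the neuron-like share was 22.3% in missense and 42.4% in wild-type libraries (adjusted p = 0.793 by fry for each of these 3 lists). Within progenitor-like cells, G2/M genes had 42 of 54 members below 0 (median −0.14, adjusted p = 0.884), among them CENPF, a kinetochore protein, at −0.63 and MKI67 at −0.60. Wild-type replicate 1 stood apart there, with 206 of 10000 UMIs in G2/M genes against 132 to 156 in the other 6 libraries, and the median was −0.03 without it. Within neuron-like cells, general neuronal genes had 14 of 15 below 0 (median −0.29, adjusted p = 0.104), among them GAP43, a growth cone protein, at −1.01, STMN2, a microtubule regulator, at −0.59 and ELAVL3, an RNA-binding protein, at −0.37.

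Notch pathway genes in neuron-like cells were among the lists closest to the threshold, with 12 of 16 above 0, a median of 0.55 and adjusted p = 0.0528 by fry. HES1, a transcriptional target, had a log2 fold change of 1.24 ± 0.33 (SE), MAML2, a coactivator, 0.96 ± 0.26, DLL1, a ligand, 0.79 ± 0.24, and MFNG, a fringe glycosyltransferase, 1.33 ± 0.41; these 4 passed adjusted over the list alone and 0 over all genes. Over the alternative settings HES1 ran from 0.52 (Leiden resolution 0.5) to 1.52 and MFNG from 0.88 (without missense replicate 1 and wild-type replicate 1) to 1.79. Radial glia markers, which mark another cell type, had 15 of 21 members above 0 in the same neuron-like sums (median 0.28, adjusted p = 0.504). Limma's fry called 0 of 38, 34 and 33 lists in all cells, progenitor-like and neuron-like cells, with 0, 1 and 5 at an unadjusted p below 0.05, and 0, 0 and 3 in its test of change in either direction. Camera with a preset correlation called 14, 2 and 6, and 0 in each with an estimated correlation (adjusted p = 0.787 for S-phase genes in all cells and 0.355 for Notch genes in neuron-like cells). Members past the threshold adjusted over the list alone were 2 higher and 0 lower, 7 and 3, and 8 and 2, not corrected for the number of lists.

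Progenitor-like cells were scored for cell-cycle phase at 1000 UMIs per cell. S-phase calls made up 33.9 ± 7.15% of missense (SD, n = 4) and 33.5 ± 6.88% of wild-type cells (n = 3, exact permutation p = 0.943), and G2/M calls 43.0 ± 4.78% and 45.4 ± 11.6% (exact p = 0.800). Without thinning the shares were 31.3% and 32.3% for S and 45.0% and 44.6% for G2/M. Thinning left out 4359 of 9759 missense and 1737 of 4401 wild-type cells. Neuron-like cells scored in the same way gave S or G2/M calls in 42.3 ± 4.68% and 42.4 ± 4.52% (exact p = 1), against 76.9% and 78.9% of progenitor-like cells, so part of such calls is background; median UMIs per cell were 891 to 1535 in progenitor-like and 991 to 2425 in neuron-like cells. Whether free RNA adds to these calls was left open, and no cycling is read from them.

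Along the chromosomes, a stretch of chromosome 1 stood out, in a scan chosen after the data were examined. From UBE2T to ELK4 (202331657 to 205631962, 3.30 Mb), 29 of 30 genes lay above 0 in all cells, with a median log2 fold change of 0.57, and 24 of 26 and 29 of 30 in progenitor-like and neuron-like cells, with medians of 0.67 and 0.78. Its genes included MDM4, an inhibitor of p53, at 0.76 ± 0.15 (SE) in all cells, BTG2, an antiproliferative p53 target, at 0.95 ± 0.22, and PIK3C2B at 1.05 ± 0.22. The 20 genes on its left had a median of 0.00 and those on its right 0.21. Of its genes 0 passed with edgeR in any of the 3 cell sets, and 17, 19 and 23 had an unadjusted p below 0.05. The edges were set where the change was largest, so the medians and shares above 0 are selected values.

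**Figure D3:**
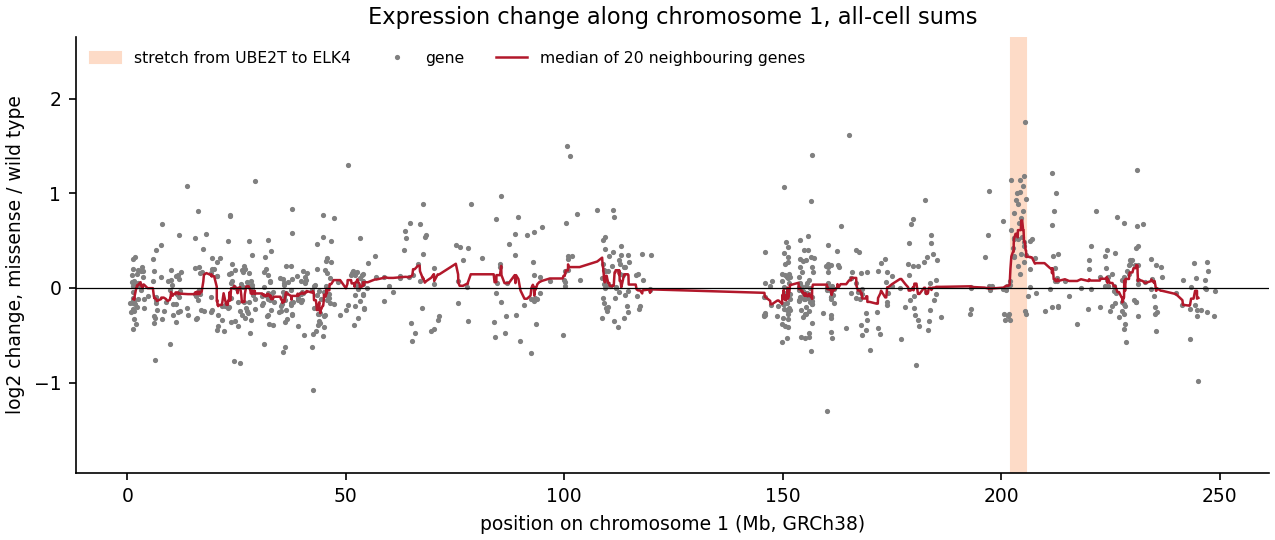
Log2 change (missense over wild type) in all-cell sums of genes with a mean of at least 20 CPM, against position on chromosome 1 (Mb, GRCh38), with 1 point per gene; the line is the median of 20 neighbouring genes and the shaded band the stretch from UBE2T to ELK4. Within the band 29 of 30 genes lie above 0, with a median of 0.57.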

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

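All tests of explanations for the near-silent genes rest on a pattern first seen in these libraries. The bounds for shared protocadherin reads and for cell make-up were written before their values were seen, and the decision to leave the shared-read test open was made after.

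In 9 of 115 comparisons 1 missense library stood far from the other 3, where chance gives 5.75. The intermediate progenitor-like share was 10.6% in missense replicate 2 and 2.92% to 3.6% in the others. In progenitor-like cells, XRCC5 stood at 9.47 in missense replicate 1 (log2 of CPM plus 2, as for all genes here; others 9.12 to 9.15) and RAD50, of the complex that binds DNA breaks, at 6.38 in missense replicate 2 (others 5.97 to 6.03). In neuron-like cells, DLL1 stood at 6.89 in missense replicate 4 (others 6.32 to 6.41), GAP43 at 10.1 in missense replicate 1 (others 9.42 to 9.52) and CBX8, a chromobox subunit of PRC1, at 4.94 in missense replicate 2 (others 5.47 to 5.55). The near-silent genes appear here as well: C17orf51 at 1.33 in missense replicate 4 and TCEAL5 at 1.32 in missense replicate 1, where the other 3 libraries had no count and stood at 1, each from 1 UMI, and PCDHA6 at 1.45 in missense replicate 2 (others 2.01 to 2.07).

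C17orf51, PCDHA6 and TCEAL5 were nearly silent in every missense library, and a difference in cell make-up is argued against: of the 7 clusters that had at least 3 libraries of each genotype, 6 had log2 changes of −4.49 or lower in the summed counts of the 3 genes (1 CPM added), and the other had 0 missense and 59 wild-type UMIs. Reads of PCDHA6 might instead be assigned to other protocadherin alpha genes, with which it shares 3′ exons; the summed counts of these genes differed by −0.29 ± 0.34 (SE), within the bound set for shared reads (under 0.5). This was counted as deciding nothing, since PCDHA6 made up 17.1% of the wild-type sum and its loss alone would move the sum by −0.27, so the bound against shared reads (a fall over 1) could not be reached. The sum without PCDHA6 was 103 ± 10.5 and 112 ± 45.5 CPM in all cells (SD, n = 4 and 3, no TMM factors), 70.9 ± 6.85 and 65.6 ± 18.1 CPM in progenitor-like and 169 ± 25.6 and 147 ± 33.0 CPM in neuron-like cells, where PCDHA4 had 57.3 ± 8.5 and 32.5 ± 9.34 CPM and PCDHA12 5.72 ± 1.44 and 18.2 ± 6.42 CPM, both picked after their values were seen; with relatives on both sides, shared reads stay open. A difference between the clones, such as promoter choice within the protocadherin cluster or a change of the loci themselves, and an effect of the RING1 change both stay open, because clone and genotype cannot be separated in these 7 libraries.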

How the results depend on the processing

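Counts of genes past the threshold depended on the tool and on the low-count filter more than on filters of barcodes. The cause of the changes was not tested except where fewer libraries or counts were used. The fits without 2 libraries, the surrogate variables and the setting without the 5% of barcodes with the most UMIs were chosen after seeing the data. Against 1, 3 and 5 genes in all cells, progenitor-like and neuron-like cells, DESeq2 called 49, 72 and 53 and edgeR without the low-count filter 205, 162 and 222, with 58 against 0 for the interaction. Limma-voom called 3 in all cells and 0 in neuron-like cells. With 1 surrogate variable 16 genes passed in progenitor-like and 25 in neuron-like cells, and with 2 surrogate variables 40, 215 and 137; neither number was estimated from the data. Leaving out missense replicate 1 with wild-type replicate 1, or with wild-type replicate 3, gave 0 in each of the 3 cell sets. Leaving out 1 library gave 0 to 2 genes in all cells, 2 to 4 in progenitor-like and 0 to 14 in neuron-like cells. In all cells at least 500 genes and 1000 UMIs per barcode gave 2, and so did a mitochondrial limit of 10%. Progenitor-like calls were 1 with libraries thinned to the smallest total, where APOO, C17orf51 and PCDHA6 all lost theirs, and 5 without the barcodes of most UMIs. The interaction had 1 call at Leiden resolution 0.5.

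Whether the numbers of the replicates pair the samples was not settled. Correlations of deviations between libraries of the same number ran from −0.03 to 0.71 over 3 pairs in all cells. The 2 libraries of replicate 2 had 0.71, 0.63 and 0.62 in all cells, progenitor-like and neuron-like cells, the highest of any library pair in each set. With the replicate number as a block, 0 genes passed in all cells and 0 in progenitor-like cells, 4 in neuron-like cells, and no list or share passed.

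Camera with a preset correlation called 14, 2 and 6 lists against 0 by fry. Leaving out 1 library gave 0 to 1 list in progenitor-like cells and 0 to 1 in neuron-like cells. In neuron-like cells 1 list passed with at least 10 CPM in 3 libraries, 1 without missense replicate 1 and wild-type replicate 3, 1 with at least 200 genes and 300 UMIs per barcode and 2 with at least 500 genes and 1000 UMIs.

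No class or phase share passed in any setting, and several differences (missense minus wild type, percentage points) changed sign. With 1 library left out the choroid plexus or roof plate-like difference ran from −20.4 to 8.0, the intermediate progenitor-like one from −1.99 to 3.94, the neuron-like one from −35.0 to 3.02, the S-phase one from −3.49 to 3.05 and the G2/M one from −6.96 to 4.15. The progenitor-like difference, 18.5 in the main setting, kept its sign but ran from 9.22 to 34.4, and was 7.61 with log values centred per library. At Leiden resolution 0.5 the choroid plexus or roof plate-like difference was 0.110 and the S-phase one −0.962. The S-phase difference was −1.01 without thinning (G2/M 0.394), −1.48 at 500 and −0.613 at 2000 UMIs per cell, −0.348 with at least 200 genes and 300 UMIs, −0.290 without called doublets and −1.08 without the barcodes of most UMIs.

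Of named genes that did not pass, RING1 in neuron-like cells ran from −0.18 to 0.23 (log2) with 1 library left out. It was 0.0869 with thinned libraries, 0.29 and 0.004 without missense replicate 1 and wild-type replicate 1 or 3, 0.13 and 0.20 with 1 and 2 surrogate variables, 0.00227 at Leiden resolution 0.5, 0.00600 with at least 200 genes and 300 UMIs and 0.0553 without the barcodes of most UMIs. RNF2 ran from −0.0353 to 0.23 in all cells with 1 library left out and was −0.23 and −0.00668 in thinned progenitor-like and neuron-like sums, where progenitor-like BRCC3 was 0.40 and PHC3 −0.20. BRCA1 was 0.00276 in progenitor-like cells with 1 surrogate variable. Over all named genes and settings 2468 values kept their sign and their side of the threshold, whatever their size. A further 159 gained and 70 lost a call, and 17 changed sign. The median of the chromosome 1 stretch ran from 0.560 to 0.647 with 1 library left out. The genes past the threshold kept their direction in every setting, with adjusted p up to 0.556. Over the settings, values moved by more than 1.5 times for several genes that did not pass. In progenitor-like cells SLC17A6 ran from 0.43 (log values centred per library) to 2.91 (thinned libraries), EGR3 from 0.40 to 1.02, BCOR from 0.20 to 0.53, PRRX1 from −2.26 to −1.06, MKI67 from −0.80 to −0.20, CENPF from −0.74 to −0.32, H2AFX from −0.92 to −0.44, EZH2 from −0.73 to −0.33 and RING1 from −0.41 to −0.02. In neuron-like cells HES1 ran from 0.52 (Leiden resolution 0.5) to 1.52 (thinned libraries), MFNG from 0.88 (without missense replicate 1 and wild-type replicate 1) to 1.79 (without wild-type replicate 3), IFI44L from 0.42 to 1.52, IFI27 from 0.67 to 2.59, GAP43 from −1.31 to −0.55 and STMN2 from −0.83 to −0.28. In all cells ANKRD20A7P ran from 5.73 to 11.4, BCOR from 0.28 to 0.54 and RING1 from −0.325 to −0.00320. Small changes were seldom detectable: 2-fold changes were recovered in 4.48%, 34.3% and 25.4% of simulated genes, where the common coefficient of variation between libraries was 0.379, 0.256 and 0.271.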

Other observations

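The tests of gene lists here were planned; the tests of explanations and the splits of the libraries were chosen after the result was seen, except that the bounds were written before the values were seen for depth and dosage of the chromosome 1 stretch and for cell make-up of the X-linked genes.

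Some members of further lists passed adjusted over the list alone, not over all genes and not corrected for the number of lists, while the lists themselves did not pass (adjusted p = 0.884 by fry for Wnt genes in progenitor-like cells and 0.793 for mid- and hindbrain genes in all cells). In progenitor-like cells WNT7A, a Wnt ligand, had a log2 fold change of 1.87 ± 0.37 (SE) and DKK3, of the Dickkopf family, 0.84 ± 0.23, and both passed adjusted over the list alone, as did the immediate early genes BTG2 (0.79, in the chromosome 1 stretch), EGR3 (0.82) and NR4A1 (0.71) in their list. SLC17A6, a glutamate transporter of neurons, had 1.45 (0.43 to 2.91 over the alternative settings), and TLE4, a corepressor of the Groucho family, and PRRX1, a mesenchymal homeobox gene, −0.77 and −1.76, each past the threshold adjusted over the list alone. In all cells GATA3, a transcription factor of the mid- and hindbrain list, had 2.29. In neuron-like cells the immediate early gene DUSP1 had 0.71, BTG2 1.34 and MYC −0.88.

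In neuron-like cells the Wnt list had 13 of 15 members above 0 (median 0.37, adjusted p = 0.104 by fry), the interferon list 5 of 7 (median 0.40, adjusted p = 0.0529) with IFI44L at 1.14 and IFI27 at 1.01, and the mesenchymal list 3 of 3 with COL5A1, a collagen, at 1.24 (adjusted p = 0.0528). Mitochondrially encoded genes had 14 of 15 members above 0 in progenitor-like cells (median 0.44, adjusted p = 0.884), heat shock genes 10 of 12 below 0 (median −0.13, adjusted p = 0.920), and cytoplasmic ribosomal proteins a median of 0.06 (adjusted p = 0.920).

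The stretch of chromosome 1 from UBE2T to ELK4 was higher in all 4 missense than in all 3 wild-type libraries. In 1 of 35 splits of the libraries, the real one, a window of 20 genes lay as far from 0 anywhere in the genome, at 0.713, 0.676 and 0.810 in all cells, progenitor-like and neuron-like cells against at most 0.631, 0.578 and 0.666, and 1 in 35 is the smallest share these splits allow. Cell make-up and depth are argued against, since the median was 0.557 or more in each of the 7 clusters with at least 3 libraries of each genotype (0.374 to 0.941 in the other 8, which had fewer) and 0.631 with every library thinned to the same total (0.576 unthinned on the same scale). A gain of 1 copy in the missense clone, or a loss in the wild type, is a candidate explanation. The 6 genes of the stretch at 2 to 20 CPM, not used to find it, had a median of 0.525. The interval of this median over genes, 0.139 to 1.14, leaves dosage open, and 8 such genes on either side had 0.385 (−0.297 to 0.560). No DNA was examined, and regional regulation under the RING1 change was not tested apart from the clone.

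Among genes placed on the chromosomes with a mean of at least 20 CPM, X-linked genes were frequent among the 100 smallest p. They numbered 22 in all cells, 24 in progenitor-like and 25 in neuron-like cells. The X chromosome held 293 of 8246 such genes in all cells, 282 of 8004 in progenitor-like and 294 of 7908 in neuron-like cells. X-linked genes below that level, such as TCEAL5, were not counted. The highest of the other splits gave 18, 22 and 19, each from missense replicate 4 grouped with the wild type. That split differs from the real one only in the side of missense replicate 4. In each set 1 of 35 splits, the real one, reached the count. Over the 293 X-linked genes with a mean of at least 20 CPM in all cells, the median was −0.0865 (95% interval over genes −0.179 to −0.0301). That lay within 0.29 either way, the bound set for a dose difference of the whole chromosome. The interval leaves out the spread between libraries, so it argues against such a difference only for these 7 libraries. A difference in make-up between clusters is argued against by the change of the class's X-linked genes within single clusters. Its median was 0.786 (interval over genes 0.645 to 1.05) to 1.04 of that in the class in 7 clusters with at least 3 libraries of each genotype. In all cells 6 were higher and 16 lower, in progenitor-like cells 11 and 13 and in neuron-like cells 11 and 14; picked after their values were seen, and without a count over all genes between them, PRDX4, APOO, EIF2S3, PCYT1B and POLA1, which start between 23664262 and 24693919, had −0.76 to −1.38 in progenitor-like cells, and MID1IP1, USP9X, CASK, TIMM17B and CLCN5, which start between 38801432 and 49922615, had 0.87 to 1.04. A difference between the clones in the regulation of X-linked genes, and an effect of the genotype, may each account for the count and stay open.

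The counts of genes past the threshold in the 3 cell sets did not exclude chance. For all cells, 2 of the 35 splits of the libraries, the real one included, gave at least the real 1 gene (highest other 1). For progenitor-like cells 3 splits, again with the real one, gave at least the real 3 (highest other 371). For neuron-like cells 2, again with the real one, gave at least the real 5 (highest other 93). For the interaction and the lists, where the real count was 0, all 35 splits reach it by construction, so this comparison decides nothing; the highest other counts were 220 genes and 6, 3 and 3 lists. The splits with 371 and 93 genes set missense replicates 2, 3 and 4 with wild-type replicate 2 against the rest, and the one with 220 missense replicates 1 and 2 with wild-type replicates 2 and 3. Such counts, many times the real ones, point to a structure of the samples that the genotype does not describe.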
